A study of Rattus norvegicus with 4 samples.

How the data were processed

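RNA of NR8383 cells from 4 biological replicates of 1 exposed group was hybridised to 1-colour Agilent rat arrays. Per the labels' protocols, cells were seeded in 25 cm² flasks for 48 h in medium with 15% serum, RNA had an integrity number above 7.5, and 100 ng was labelled with Cy3. Per the labels, the cells had been through 20 passages. Every sample's group and replicate number came from the labels. The cells incubated without particles that the series design mentions were not analysed here, so no comparison between groups was made. All 4 arrays lay on 1 slide with 1 scan, so slide and scan could not differ, and the position on the slide cannot be told apart from the replicate.

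The deposited files hold, for each spot, intensity on a linear scale that Agilent Feature Extraction 11.0.1.1 had computed, per the file headers and the submitters' processing notes. The processed intensity was background-subtracted and detrended within each array, per the file headers, and low spots hold a small positive floor value in its place. It was not normalized between arrays. Background differed between arrays. On replicate 1 the 99th percentile of the 308 negative control spots was 27.1, against 7.40, 4.95 and 6.25 on replicates 2, 3 and 4. The lowest processed intensity of a spot marked well above background was 22.3, 11.3, 10.8 and 12.1 on the 4 arrays, and a gene without such a mark has only a bound there. The slope of the spike-in series was 0.887, 0.886, 0.881 and 0.869, outside the range that the software itself accepts on all 4 arrays.

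From these files, log2 of the processed intensity was averaged over the spots of a probe, leaving out control spots and spots marked non-uniform, which were 1, 7, 0 and 6 on replicates 1 to 4. Of the 45598 probes, 43279 had 1 spot, 969 had 2 and 1350 had 10. The array's 75th percentile over probes was then subtracted. Under 41% of probes were detected on any array, a case in which a percentile over detected probes is often preferred. The percentile over all probes had been fixed beforehand and was kept, with the other as an alternative. Replicates were compared with each other before use, and the Pearson correlation across tested genes, which are not independent replicates, lay between 0.981 and 0.993 for the 6 pairs.

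The files name probes by accession and carry no symbol, so accessions without versions were matched to a table of RefSeq genes of assembly GRCr8, used for names only. This named 21109 probes (46.3%) and 16581 genes. Other probes kept their accession, which gave 39506 genes and unnamed transcripts in all. For a gene with several probes, the probe with the highest mean was used, and a gene counted as not well above background only if all of its probes were. Among 5015 genes with several probes, 1095 had some but not all of them well above background on all arrays. A probe was well above background if the software's mark was set on at least 50% of its spots.

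Genes well above background on at least 2 arrays entered the variance test, 14913 in all. An intercept was fitted with lmFit of limma 3.58.1 in R 4.3.3, and each gene's residual variance was set against the prior of squeezeVar with a trend on mean level, not robust (prior degrees of freedom 6.52), in a one-sided F test with Benjamini-Hochberg adjustment and a threshold of 0.05. The 27 gene lists, among them 7 lists of markers of other cell types, were compared with the tested genes by a one-sided Fisher's exact test. For lists with at least 3 tested members, 21 in all, the range over arrays of the list's median deviation was set against 10000 random lists drawn from 20 bins of mean level. The adjustment of the resulting shares over lists had not been fixed beforehand, while the range and its percentile had.

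Both tests were tested on data simulated from the mean levels of these 14913 genes and the fitted prior, with independent normal noise. That is the model the variance test assumes, so the simulation cannot show its error rate on real arrays. With no effect, the variance test made 0 calls. With 200 genes given 4 times their SD it recovered 0, and with 8 times their SD 58 (29%), with 0 false calls in both, so that it has low power with 4 arrays. With no effect 0 of 21 lists passed the range test. With 1 list lowered by 0.3 log2 units on replicate 1, that list and 0 others passed. The simulated genes varied independently, so these results do not cover genes that vary together between arrays.

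Apart from the additions named as such, the lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the first 3 members of each list with their level, or as not matched to a probe, other list members past the threshold of the variance test, the 10 named genes with the smallest adjusted p that were well above background on all arrays, and the members behind a count of 5 or fewer. Some genes that the rule takes are not reported here. Names from the RefSeq table stand in the rule for names in the files. The alternatives were other normalizations, background correction, probe rules, filters, priors, detection marks, and leaving out each replicate in turn. Mean spot intensity is not a column of these files, so the alternative background correction (normexp with an offset of 50) used the median intensity instead, a choice made after seeing the files. The percentile over all spots, the robust prior with quantile normalization, an exchange of the prior degrees of freedom between the 75th percentile and quantile normalization, the range of the stress response list without replicate 1 under the other scalings, and a comparison of array profiles of unnamed sequences with 1000 random lists were also chosen after seeing the data. Coordinates were left out because the array design and the gene table use different builds.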

Results

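Gene expression was measured in NR8383 cells, a continuous line of rat alveolar macrophages, after 4 h with carbon black Printex 90, a powder of aggregated carbon nanoparticles used as a model particle in inhalation toxicology. The dose was given in the labels as 0.9 cm²/cm². The series asked how carbon black changes transcript levels relative to cells incubated without it. The arrays analysed here came from 1 group, 4 biological replicates of exposed cells, each on its own 1-colour array, and the incubations without particles were not analysed here. No fold change or treatment effect was therefore computed, and the values below are levels in exposed cells, their spread between replicates and the share of genes with signal above background.

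Each array held 58717 non-control spots for 45598 probes. The scanner software marked 17079, 18641, 17319 and 17084 probes as well above background on replicates 1, 2, 3 and 4, between 37.5% and 40.9% of the probes. The 75th percentile of processed intensity over all spots was 546, 503, 330 and 317 on the same arrays, and no spot was saturated. Levels are log2 processed intensity minus the array's own 75th percentile over probes, given as mean ± SD over the 4 arrays, so that 0 is the 75th percentile. The number of arrays limits the precision of every SD. A level describes the signal of that gene's own probe and cannot be set against the level of another gene, because probes differ in how strongly they bind.

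The macrophage programme was broadly detected. Of 39506 genes and unnamed transcripts, 13440 (34.0%) were well above background on all 4 arrays, and of 16581 named genes, 7947 (47.9%) were. Of 339 members of the 27 gene lists with a probe, 233 were well above background on all 4 arrays, 18 on some arrays and 88 on none. The median SD between replicates was 0.161 log2 units over the 14913 genes tested, and 90% of these SDs lay between 0.059 and 0.58. Without the filter on dim probes the median SD was 0.327. Probes spotted repeatedly within an array varied less, with a median SD of 0.087 between their spots against 0.156 between arrays for the same 2319 probes.

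**Figure D1:**
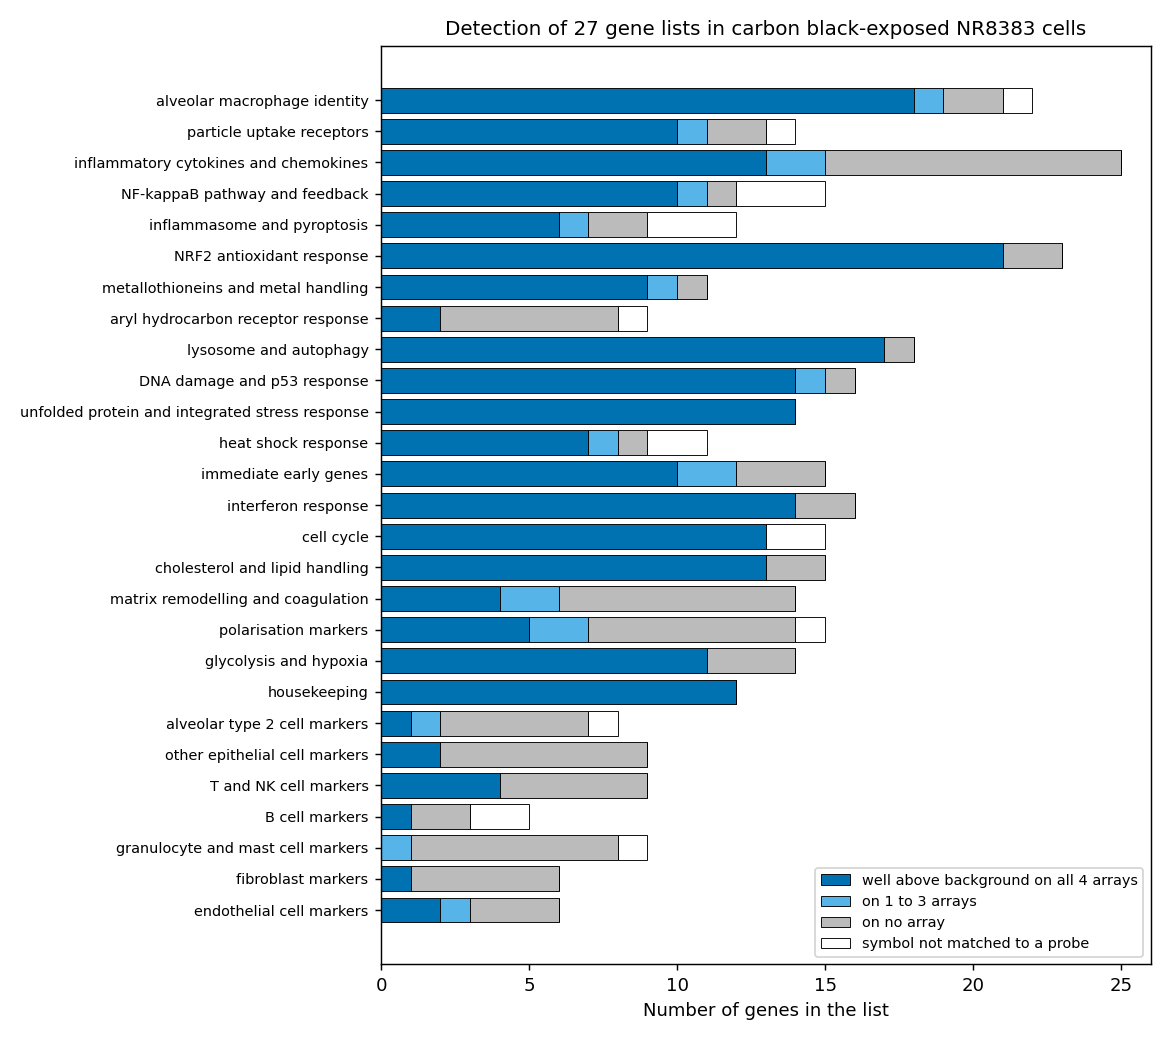
Number of genes (x axis) of each of the 27 gene lists (y axis) that were well above background on all 4 arrays, on 1 to 3 arrays or on no array, or whose symbol was not matched to a probe. Every measured member of the housekeeping list (12 of 12) and of the unfolded protein and integrated stress response list (14 of 14) was detected on all 4 arrays, against 0 of 8 measured granulocyte and mast cell markers.

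Of 21 measured genes of alveolar macrophage identity, 18 were well above background on all 4 arrays. The lysosomal glycoprotein gene Cd68 had a level of 5.56 ± 0.15 (SD, n = 4), the leukocyte phosphatase gene Ptprc 4.70 ± 0.11 and the myeloid transcription factor gene Spi1 3.84 ± 0.063. Chi3l1 was well above background on 1 array, Adgre1 and Car4 on none, and Itgax was not matched to a probe. Of 13 measured particle uptake receptors, 10 were detected on all arrays. The scavenger receptor genes Cd36 and Msr1 had levels of 6.94 ± 0.12 and -0.75 ± 0.21. Marco, a scavenger receptor that binds unopsonised particles, and Colec12 were not well above background on any array, Cd163 was so on 1 array, and Stab1 was not matched to a probe.

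Inflammatory mediators were divided. Of 25 measured cytokine and chemokine genes, 13 were well above background on all 4 arrays, Nos2 on 2 arrays and Il10 on 1. The cytokine genes Tnf and Il1b had levels of 3.99 ± 0.22 and 4.13 ± 0.12, and the neutrophil chemokine gene Cxcl2 2.33 ± 0.090. The other 10 were not well above background on any array. They were Il6, Il12b, Il23a, Cxcl1, Ccl20, Csf1, Csf2, Lif, Osm and Ptgs2, which were named after their values were seen. Of 12 measured NF-kappaB pathway genes, 10 were detected on all arrays, with Nfkb1 at 2.56 ± 0.17 and its inhibitor gene Nfkbia at 3.84 ± 0.31. Birc3 was well above background on 2 arrays and Traf1 on none, and Tnfaip3, Relb and Nfkbiz were not matched to a probe. Of 9 measured inflammasome and pyroptosis genes, 6 were detected on all arrays. The sensor gene Nlrp3 had a level of 1.21 ± 0.069, the protease gene Casp1 1.99 ± 0.043 and the adaptor gene Pycard 2.52 ± 0.14. Txnip was well above background on 1 array, P2rx7 and Panx1 on none, and Gsdmd, Nlrc4 and Aim2 were not matched to a probe.

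Oxidative and metal stress genes were mostly detected. Of 23 measured genes of the NRF2 antioxidant response, 21 were well above background on all 4 arrays, and Gclm and Gsta4 on none. Heme oxygenase 1 (Hmox1) had a level of 8.33 ± 0.53, from 7.63 on replicate 1 to 8.90 on replicate 4, and the quinone reductase gene Nqo1 1.33 ± 0.099. The spread of Hmox1 did not pass the variance test (adjusted p = 0.214, limma). Of 11 measured metallothionein and metal handling genes, 9 were detected on all arrays, Slc39a14 on 2 and Slc40a1 on none. The metallothionein genes Mt1 and Mt2A had levels of 4.08 ± 0.14 and -1.59 ± 0.28, and the ferritin heavy chain gene Fth1 8.74 ± 0.38. The aryl hydrocarbon receptor response had signal for 2 of 8 measured genes, Arnt and Nqo1. Its receptor gene Ahr and the cytochrome P450 genes Cyp1a1 and Cyp1b1, its classical targets, were not well above background on any array, and Tiparp was not matched to a probe.

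Of 18 measured lysosome and autophagy genes, 17 were well above background on all 4 arrays, and Ctsk on none. Lysosomal membrane protein Lamp1 had a level of 6.72 ± 0.14, the protease gene Ctsd 8.87 ± 0.11 and the autophagy receptor gene Sqstm1 7.40 ± 0.27. Of 16 measured DNA damage and p53 response genes, 14 were detected on all arrays, Rrm2b on 1 and Btg2 on none. The cell cycle inhibitor gene Cdkn1a had a level of 5.69 ± 0.12, the p53 ubiquitin ligase gene Mdm2 1.34 ± 0.082 and Gadd45a 3.24 ± 0.38. Of 13 measured cell cycle genes, 13 were detected on all arrays, with Mki67 at 4.51 ± 0.16 and Pcna at 4.46 ± 0.11, and Top2a and Mcm5 were not matched to a probe.

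All 14 measured genes of the unfolded protein and integrated stress response were well above background on all 4 arrays. The endoplasmic reticulum chaperone gene Hspa5 had a level of 5.70 ± 0.077, and the stress transcription factor genes Ddit3 and Atf4 4.34 ± 0.21 and 6.62 ± 0.23. Of 9 measured heat shock genes, 7 were detected on all arrays, with Hspa8 at 9.34 ± 0.12 and Hsp90aa1 at 7.12 ± 0.11. Hsph1 was well above background on 3 arrays and Hspb1 on none, and Hspa1b and Dnajb1 were not matched to a probe. Of 15 measured immediate early genes, 10 were detected on all arrays, with Fos at -1.09 ± 0.32 and Jun at 3.07 ± 0.088. Egr3 and Klf2 were well above background on 1 array each, and Egr1, Fosl1 and Zfp36 on none. Of 16 measured interferon response genes, 14 were detected on all arrays, with Irf7 at 1.99 ± 0.098 and Ifit3 at 0.033 ± 0.51. Ifit1 and the interferon gene Ifnb1 were not well above background on any array.

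Of 15 measured cholesterol and lipid handling genes, 13 were well above background on all 4 arrays, and Scd and Fasn on none. The cholesterol exporter gene Abca1 had a level of -0.0060 ± 0.21. Of 14 measured glycolysis and hypoxia genes, 11 were detected on all arrays, with the hexokinase gene Hk2 at 0.034 ± 0.20 and the glucose transporter gene Slc2a1 at 5.75 ± 0.21. Vegfa, Hk1 and Egln3 were not well above background on any array. The matrix remodelling and coagulation list had signal on all arrays for 4 of 14 measured genes, which were Mmp12 at 0.41 ± 0.49, Timp1 at -2.08 ± 0.14, Mmp9 and Plaur. Mmp14 and Plau were well above background on 1 array each, and 8 genes, among them Spp1, on none. Of 14 measured polarisation markers, Arg1 (3.19 ± 0.16), Il4r, Ccl22, Socs3 and Irf4 were detected on all arrays, Ccl17 on 3 and Cd80 on 1, and Chi3l3 was not matched to a probe. The other 7 were not well above background on any array. They were Retnla, Socs1, Cd86 and the antigen presentation genes RT1-Ba, RT1-Da, Cd74 and Ciita, of which all but Retnla were named after their values were seen.

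All 12 housekeeping genes were well above background on all 4 arrays. Actb had a level of 9.09 ± 0.26, Gapdh 9.60 ± 0.14 and Hprt1 5.19 ± 0.037.

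Markers of other lung and blood cell types were mostly without signal. Of 48 measured markers in 7 lists, 11 were well above background on all 4 arrays, 3 on some and 34 on none. Among alveolar type 2 cell markers, Napsa was detected on all arrays and Sftpd on 1, while Sftpc, Sftpb, Sftpa1, Lamp3 and Slc34a2 were not well above background on any, and Abca3 was not matched to a probe. Among other epithelial markers, Ager and Foxj1 were detected on all arrays and 7 on none, including Epcam, Cdh1 and Krt8. Among T and NK cell markers, Cd3d (-1.51 ± 0.50), Lck, Nkg7 and Gzmb were detected on all arrays, and Cd3e, Cd3g, Cd2, Cd5 and Cd8a on none. The B cell factor gene Pax5 was detected on all arrays, Cd79b on none, and Ms4a1 and Cd79a were not matched to a probe. S100a8 was well above background on 2 arrays, with levels of -4.31, -0.27, -2.58 and -0.40 on replicates 1 to 4, of which those on the other 2 arrays are only bounds. The 7 other measured granulocyte and mast cell markers, including S100a9, were not well above background on any array, and Mpo was not matched to a probe. Of fibroblast markers, Dcn was detected on all arrays, and Col1a1, Col1a2, Col3a1, Lum and Pdgfra on none. Of endothelial markers, Pecam1 (1.51 ± 0.42) and Vwf (4.09 ± 0.037) were detected on all arrays, Cdh5 on 2, and Kdr, Tek and Cldn5 on none.

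**Figure D2:**
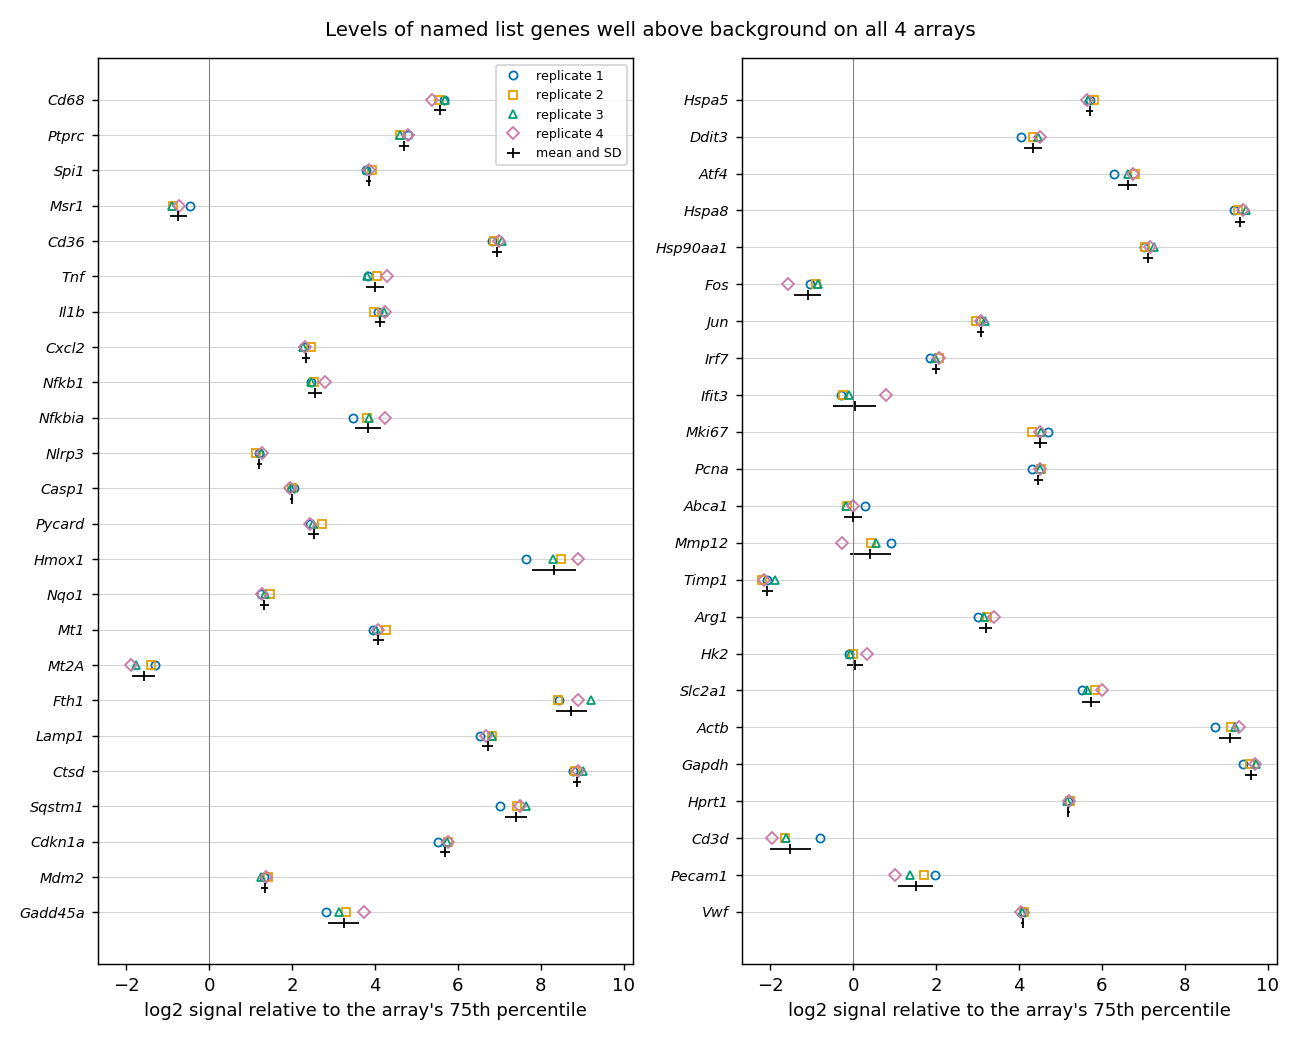
Level on each replicate array (x axis, log2 signal relative to the array's 75th percentile) of named members of the gene lists that were well above background on all 4 arrays (y axis). Coloured symbols are the replicates, and the black tick with its bar below them is the mean and SD. Hprt1 (SD 0.037) and Vwf (SD 0.037) lay close together over the replicates, while Hmox1 (SD 0.53) and Ifit3 (SD 0.51) spread more widely.

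The spread between replicates was then tested gene by gene against the spread of genes of like brightness. Expression of 71 genes and unnamed transcripts varied more than expected (adjusted p under 0.05, limma), and 62 of them had their lowest level on replicate 1. Of the 71, 66 were well above background on all 4 arrays. Only 8 of the 71 had a gene name here. They were Alcam, a cell adhesion molecule, with levels of 3.40, 0.36, 3.03 and 2.74 on replicates 1 to 4 (adjusted p = 0.0085), Basp1, a membrane-bound signalling protein, with 6.97, 8.28, 7.86 and 9.67 (adjusted p = 0.014), and Rassf4, Slc25a3, Zdhhc18, Mitf, Tent5c and Stim1. The melanocyte and macrophage-lineage transcription factor gene Mitf had levels of 3.15, 4.96, 5.05 and 4.89 (adjusted p = 0.023), and the poly(A) polymerase gene Tent5c 1.52, -1.21, -1.61 and -1.23 (adjusted p = 0.035). Rassf4 and the mitochondrial phosphate carrier gene Slc25a3 had their lowest levels on replicate 4, 3.03 and 2.20, against highest levels of 5.16 on replicate 3 and 4.65 on replicate 1 (adjusted p = 0.018 for both). The palmitoyltransferase gene Zdhhc18 was highest on replicate 1 at 6.13 and lowest on replicate 3 at 4.17 (adjusted p = 0.022), and the calcium sensor gene Stim1 was highest on replicate 1 at 1.90 and lowest on replicate 4 at -0.39 (adjusted p = 0.042). Next in order, Grin2d (SD 0.77, adjusted p = 0.051) and Serpina5 (SD 1.53, adjusted p = 0.054) did not pass.

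Of the 71, 3 had a second probe with signal, and 2 of these second probes had a variance ratio above the 95th percentile of all tested probes. They were that of an unnamed Ensembl transcript, with an SD of 1.01, and that of Mitf, with an SD of 0.29. This Mitf probe had levels of 3.73, 3.07, 3.55 and 3.60 on replicates 1 to 4. It was highest on replicate 1, where the Mitf probe that passed was lowest. The second probe of Zdhhc18 had an SD of 0.15, and that of Grin2d, which did not pass, an SD of 0.021. At an unadjusted p under 0.05 (limma), 755 genes passed, against 746 expected under the fitted prior. The prior was estimated from these same genes, so the likeness of the 2 counts is no independent comparison with chance. Without replicate 2 none of the 8 named genes passed (adjusted p between 0.056 for Slc25a3 and 0.889 for Alcam, limma). Alcam had stood apart there, at 0.36 against 2.74 to 3.40 on the other arrays. The spread of the called sequences as a set was not smaller, with a median SD of 1.45 over 70 of them against 1.24 with all arrays. The prior degrees of freedom fell from 6.52 to 4.84, so the loss does not show that the other calls rested on replicate 2. Without replicate 1 Zdhhc18, Mitf and Tent5c did not pass (adjusted p = 0.944, 0.993 and 0.993), and without replicate 4 Basp1, Rassf4, Slc25a3 and Stim1 did not (adjusted p = 0.194, 0.991, 0.203 and 0.467). The count of 71 changed with the scaling, the model of the spread and single arrays. It was 1 with quantile normalization, 1 with cyclic loess, 0 with the 75th percentile over detected probes and 1 with that over all spots. It was 235 with another background correction, 356 without the filter on dim probes, 207 with a robust prior, 0 with a prior without trend, and 27, 161 and 43 without replicates 2, 3 and 4. Without replicate 1 it was 91, of which 60 were among the 71.

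**Figure D3:**
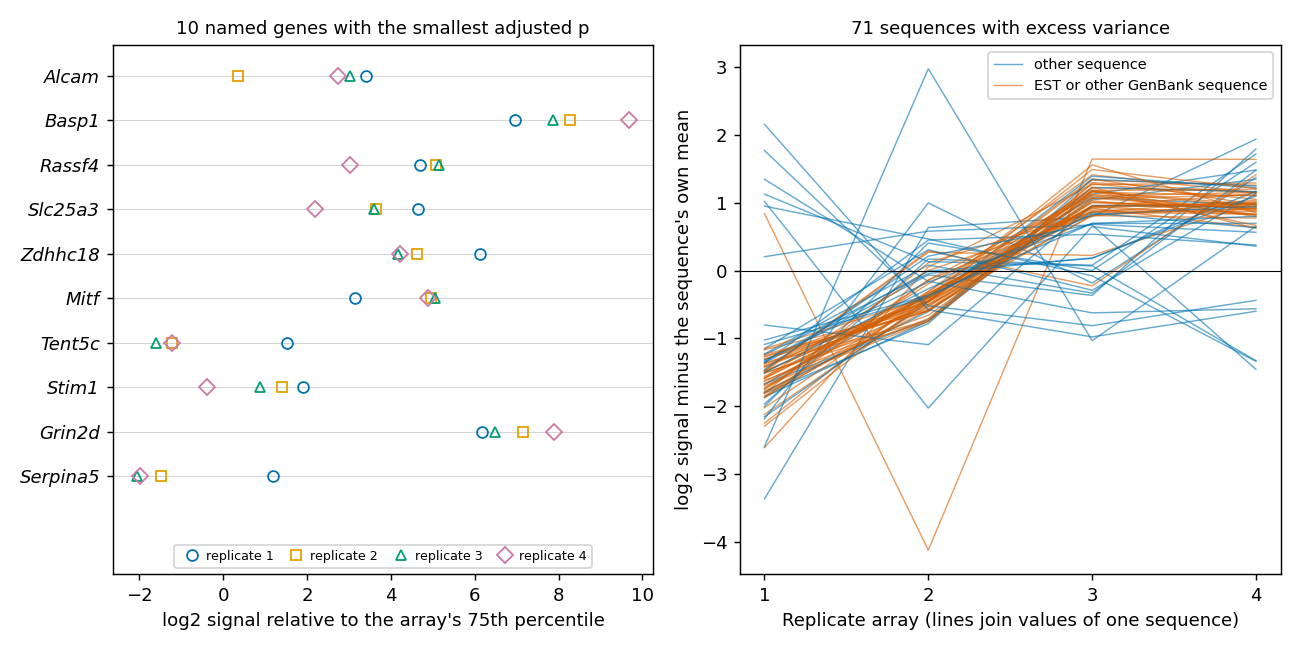
Left, level on each replicate array (x axis, log2 signal relative to the array's 75th percentile) of the 10 named genes with the smallest adjusted p in the variance test (y axis), of which Grin2d (adjusted p = 0.051) and Serpina5 (adjusted p = 0.054) did not pass. Right, deviation of each of the 71 sequences with excess variance from its own mean (y axis, log2) on replicates 1 to 4 (x axis), with a line joining the values of 1 sequence and the 41 probed on expressed sequence tags or other GenBank sequences in orange. The median deviation of these 41 was -1.58 on replicate 1, -0.45 on replicate 2, 1.06 on replicate 3 and 0.97 on replicate 4.

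None of the 71 was a member of any of the 27 gene lists, so that 0 lists passed the one-sided Fisher's exact test, adjusted or not. Only 8 of the 71 had a gene name, and the lists hold named genes only. The test could therefore hardly pass, and no conclusion about pathways is drawn from it. Of 240 list members tested with limma, 0 passed after adjustment over all genes and 22 had an unadjusted p under 0.05. That is a larger share than the 755 of all 14913 tested genes. Adjusted over the list alone, 5 passed, namely Trib3 (0.0078), Fdft1 (0.044), Pax5 (0.047), S100a8 (0.00043) and Pecam1 (0.046). Pax5 and S100a8 were each the only tested member of their list. The p of S100a8 rests on values not well above background on 2 arrays and is not evidence of excess variance, while the other 4 were well above background on all arrays. Trib3, a pseudokinase induced in the integrated stress response, had levels of 3.52, 4.82, 4.68 and 4.99 on replicates 1 to 4.

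The unfolded protein and integrated stress response list had a wider range between replicates than random lists, although 0 of its members passed the variance test over all genes. The median deviation of the 14 members from their own means was -0.22 on replicate 1, 0.10 on replicate 2, 0.0070 on replicate 3 and 0.13 on replicate 4. The range of 0.353 lay at the 99.9th percentile of 10000 random lists matched on level, and its share of random lists, adjusted over 21 lists, was 0.023. Replicate 4 minus replicate 1 was above 0 for 10 members, among them Atf4 with 0.45 and Ddit3 with 0.47 log2 units. It was below 0 for the other 4, with -0.074 for the chaperone gene Hspa5, -0.27 for Xbp1, -0.18 for Pdia4 and -0.27 for the chaperone gene Hsp90b1. The median absolute difference between these arrays was 0.213 over tested genes. Replicate 1 stood lower in other lists too, with a median deviation below 0 in 18 of 21 lists, among them -0.23 for polarisation, -0.20 for metal handling and -0.073 for housekeeping, although this number was 11 with quantile normalization and 8 with another background correction. The list did not pass without replicate 1 (percentile 25.98), without replicate 4 (98.3rd percentile, adjusted share 0.173) or with another background correction (17.0th percentile), and over the 9 other settings with all arrays its adjusted share lay between 0.0021 and 0.992. With quantile normalization, cyclic loess and the percentiles over detected probes and over all spots, its percentile without replicate 1 lay between 98.5 and 99.7. There it passed with quantile normalization and cyclic loess (adjusted shares 0.029 and 0.028). It did not pass with the percentiles over detected probes and over all spots (adjusted shares 0.120 and 0.092).

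The other 20 lists did not pass. The NF-kappaB list came next with a range of 0.330 (99.2nd percentile, adjusted share 0.077), then the immediate early genes with 0.343 (98.9th percentile, adjusted share 0.077). Both had their lowest median on replicate 1, -0.22 and -0.19, and their highest on replicate 4, 0.11 and 0.15. Of 9 other settings with all arrays, the NF-kappaB list passed in 5 and the immediate early genes in 3. Without replicate 1 their ranges were only 0.075 and 0.124 (percentiles 18.1 and 57.9). With each of the 4 replicates left out in turn, they passed in 2 cases and 1 case. The metal handling and polarisation lists had ranges of 0.317 and 0.392 (98.0th and 97.6th percentiles, adjusted share 0.102 for both). The NRF2 list had a range of 0.217 (91.1st percentile), which was 0.0088 without replicate 1 (0.05th percentile). The housekeeping list had a range of 0.121 (8.05th percentile), the macrophage identity list 0.096 (3.88th percentile), the inflammasome list 0.021 (0.15th percentile) and the interferon list 0.013 (0.08th percentile). Over the 9 other settings the range of the interferon list lay between 0.012 and 0.209 (percentiles 0.05 to 65.2). A small range of medians does not mean that each member was steady. The median SD of the 14 tested interferon genes was 0.204, against 0.161 over all tested genes. Of them 3, Ifit3, Isg15 and Rsad2, had an unadjusted p under 0.05 (limma), and each was highest on replicate 4. The remaining lists lay between the 16.6th percentile, for cytokines and chemokines, and the 89.1st, for glycolysis and hypoxia. The number of lists that passed was 7 with the 75th percentile over detected probes and 7 with that over all spots, where the NF-kappaB, immediate early, cytokine, NRF2, metal handling and glycolysis lists passed beside the stress response list. The cytokine list had ranges of 0.237 and 0.225 there (99.4th and 98.9th percentiles, adjusted shares 0.030 and 0.045), against 0.114 with the percentile over probes. The number lay between 0 and 3 with every other setting tried. Random lists of unrelated genes do not copy the co-regulation within a pathway, so a percentile describes these 4 arrays only.

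**Figure D4:**
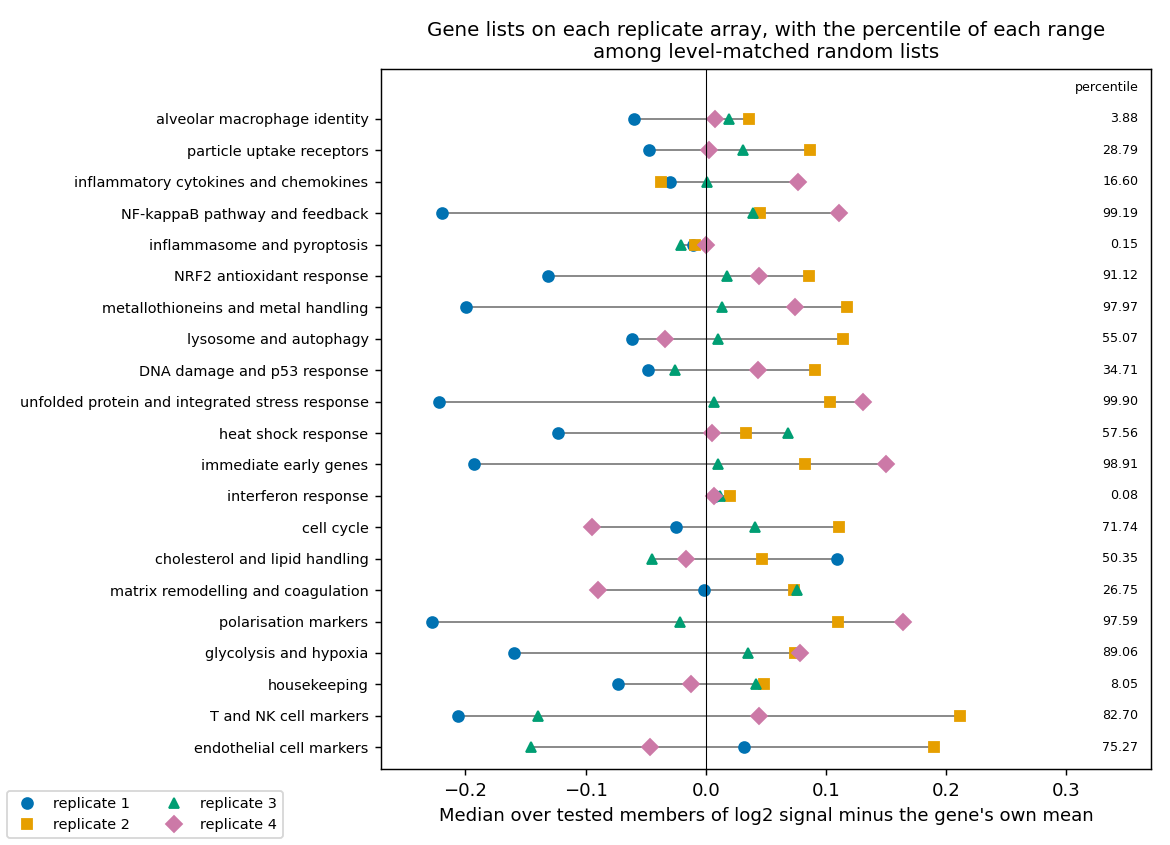
Median over the tested members of each of 21 gene lists (y axis) of the log2 signal minus the gene's own mean (x axis) on each replicate array, with a grey line over the range and, at the right, the percentile of that range among 10000 level-matched random lists. The unfolded protein and integrated stress response list runs from -0.22 on replicate 1 to 0.13 on replicate 4.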

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

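Tests of explanations were chosen only after the result was seen, except those of replicate 1 standing apart under the original scaling and of local spot defects by second probes. Among 59 named genes, 21 lists and 6 array measures checked for a single array far from the other 3, chance alone would pick out about 1 in 20. The gap of the extreme array made up 0.881 of the whole range for Cdkn1a and 0.895 for Pcna, both lowest on replicate 1, at 5.51 and 4.31. It was 0.831 for Ifit3, highest on replicate 4 at 0.79. For Mitf (0.916) replicate 1 lay lowest and for Tent5c (0.873) highest. The number of probes well above background stood apart on replicate 2 (0.846, 18641 probes), and the 99th percentile of negative controls on replicate 1 (0.890, 27.1). No list stood apart in this way.

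Probes for the external control RNA ERCC-00148, which are control spots left out of all results, carried signal on all 4 arrays. Their mean intensity was 28.4 over the arrays, and 32.8, 35.0, 21.7 and 23.9 on replicates 1 to 4, between 1.21 and 4.74 times the 99th percentile of negative controls. It was the only 1 of 96 such sequences above that level on all arrays.

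The median deviation of the 14 genes of the unfolded protein and integrated stress response was lowest on replicate 1 and highest on replicate 4. Scaling between arrays is argued against as the whole cause, since the list's range lay at the 100th percentile with quantile and with cyclic loess normalization, but with another background correction the range was 0.255 instead of 0.353 and most random lists had a larger one (17.0th percentile). The housekeeping list also shifted with that correction, from 0.14 on replicate 2 to -0.13 on replicate 4 (range 0.263, 16.9th percentile). Random lists were thus wide there too, so the low percentile does not describe the stress list alone. Whether replicate 1 alone carries the pattern stays open, because the percentile without it was 25.98 with the original scaling but between 98.5 and 99.7 with 4 others, where replicate 4 deviated about as far as replicate 1 (0.16 and -0.18 with quantile normalization). Of these 4, quantile normalization and cyclic loess let the list pass without replicate 1 (adjusted shares 0.029 and 0.028). The percentiles over detected probes and over all spots did not (adjusted shares 0.120 and 0.092). The list also missed the threshold without replicate 4 (98.3rd percentile, adjusted share 0.173). No biological explanation was tested, since the labels give replicate cultures no condition that differs, and whether the cultures or the arrays differed stays open.

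The 71 sequences with excess variance were mostly unnamed, and 58 of them (81.7%) were probed on sequences without an NM or XM mRNA accession, against 28.1% of the other tested sequences. This excess lay in expressed sequence tags and other GenBank sequences, which were 57.7% of the 71 against 5.55% of all tested. Ensembl transcripts (16.9% against 17.1%) and RefSeq non-coding sequences (7.04% against 5.77%) were near their tested share. Their median SD was 1.24 before and 1.27 after quantile normalization, although only 1 call remained. Scaling moves sequences of like brightness together, and the 71 were picked for a spread beyond that of like brightness. Their median SD could therefore hardly fall, and no conclusion about scaling as its source is drawn from it. The calls ended with the prior degrees of freedom, which fell from 6.52 to 4.61, since all 71 were among 103 calls with quantile normalization at 6.52, and 0 were called with the 75th percentile at 4.61. The 41 probed on expressed sequence tags or other GenBank sequences had similar profiles over the arrays, with a mean correlation of 0.933, which argues against independent defects of single spots as their source. The 786 such sequences without excess variance also went together more than all 1000 level-matched random lists (mean correlation 0.054 against at most 0.040, 100th percentile). A source of signal shared by some of these probes is therefore a candidate explanation, but so low a correlation does not show how many. The random lists were not matched on spread. For the other sequences with excess variance local spot defects stay open, since only 3 second probes could be checked, too few to decide. Of these, 66.7% varied more than the 95th percentile of probes, but the test counted spread and not likeness to the probe that passed. The second probe of Mitf, counted among them, was highest on replicate 1 (3.73), where the Mitf probe that passed was lowest (3.15). No biological explanation was tested.

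Of markers of other cell types, 11 of 48 were well above background on all arrays, among them Napsa, Ager, Foxj1, Cd3d, Lck, Pax5 and Dcn, and the granulocyte gene S100a8 was so on 2 arrays. Of the 15 measured first members of the epithelial, T and NK, B, granulocyte and mast cell, and fibroblast lists, 1 (Cd3d) was, and Sftpc, Krt8, Col1a1, Cd3e, Cd79b, S100a9 and the mast cell genes Cpa3 and Ms4a2 had no signal above background. This count pooled several types and its bound was set after the values were seen, so it decides on no single type. As far as these probes work, which no sample here shows, the missing Sftpc, Krt8, Col1a1, Cpa3 and Ms4a2 signal argues against epithelial, fibroblast and mast cells as the source. The reason is that cells bring their abundant transcripts along. For granulocytes the missing S100a9 signal does so less, since S100a8, also a first member, had signal on 2 arrays. By these markers alone T cells stay open, since Cd3d and Lck had signal although Cd3e, Cd3g and Cd5 did not. B cells stay open too, since Ms4a1 and Cd79a had no matched probe and Pax5 had signal, although Cd79b did not. Of 5 members of the T and NK list that NK cells also express, 3 (Lck, Nkg7 and Gzmb) were well above background on all arrays. Cd2 and Cd8a were so on none. These markers alone therefore do not tell NK cells apart from transcription of these genes in the line itself. Kdr, Tek and Cldn5, without signal on any array, argue against endothelial cells in the same way. However, 2 of the 3 first endothelial markers (Pecam1 and Vwf) were well above background on all arrays and Cdh5 on 2. That lies between the bounds set for the test, so these markers alone do not tell endothelial cells apart from such transcription either. The samples were passaged cultures of a continuous macrophage line, not lung tissue. That design names no source of T, B, NK or endothelial cells other than contamination of a culture, which was not tested. The markers with signal are therefore no evidence that such cells were present. No biological explanation was tested, and how many of the listed markers this cell line expresses by itself was not analysed here.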

How the results depend on the processing

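No paired analysis was possible because the samples form 1 group. The normexp alternatives on mean intensity were not run. Those on median intensity, the percentile over all spots, the robust prior with quantile normalization, the exchanged prior degrees of freedom and the other scalings without replicate 1 were chosen after seeing the data. The number of genes with excess variance was 235 with normexp on median intensity, 1 with quantile normalization, 1 with cyclic loess, 0 with the 75th percentile over detected probes, 1 with that over all spots, 356 without the filter on dim probes, 207 with a robust prior, 0 with a prior without trend, 22 at an adjusted p under 0.01, 0 with the prior degrees of freedom of quantile normalization, and between 27 and 161 without 1 replicate. All 71 genes were among the 235, the 356, the 207 and the 161. It stayed within 1.5 times of 71 with the mean over probes (59), genes detected on all arrays (93), no spot set aside (71), the robust prior with quantile normalization (87), quantile normalization with the original prior degrees of freedom (103) and without replicate 1 (91). With the mean over probes, however, Zdhhc18, Mitf, Tent5c and Stim1 no longer passed (adjusted p = 0.416, 0.526, 0.051 and 0.069, limma). The number of lists that passed the range test was 0 with normexp, 2 with quantile normalization, 3 with cyclic loess, 7 with detected probes, 7 with all spots, 2 with genes detected on all arrays, and between 0 and 3 without 1 replicate. The stress response list passed in 8 of 9 settings over all 4 arrays. The median SD was 0.327 without the filter on dim probes and between 0.133 and 0.170 without 1 replicate. The within-array SD was 0.110 with normexp and 0.0746 for probes detected on all arrays. Apart from the prior degrees of freedom behind the change with quantile normalization, the cause of these changes was not tested.

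Genes detected on all arrays numbered between 12345 and 17311 over the alternatives, list members between 221 and 251, and 0 lists passed Fisher's exact test under any. With the main setting that test could hardly pass, because only 8 of the 71 calls had a gene name. Of adjusted p values of the 10 named variance genes over the alternatives, 74 no longer passed, 15 newly passed and 101 kept their side. Of the list results, judged by the adjusted share of random lists, 5 no longer passed, 19 newly passed and 250 kept their side. That adjustment had not been fixed beforehand. The 80 named levels shifted by a median of -3.52 with the percentile over detected probes, -2.36 over all spots and -0.56 with normexp, and with normexp 53 moved from that shift by more than their SD. Background, highest on replicate 1, sets the lowest level that could be read.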
